A study of Mus musculus with 3 samples.

How the data were processed

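The study profiled cancer cells sorted from primary mammary tumours of MMTV-PyMT mice on the FVB background, a strain in which the polyoma middle T oncogene is expressed in the mammary epithelium. Per the labels' protocols, tumours were digested with collagenase, cells staining for CD45, CD31 or the dead-cell dye 7AAD were depleted, and cells were then selected on CD24 and CD90. Total RNA was labelled with biotin and hybridised to Illumina mouse bead arrays. The 3 arrays analysed here are 2 of CD24+CD90- cells and 1 of CD24+CD90+ cells. The labels do not say whether they come from separate animals. The p-values rest on the spread between the 2 CD24+CD90- arrays, pooled in part over genes, and that spread may be technical.

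The deposited intensity values are the mean brightness of each probe's beads on a linear scale, with no background subtracted and no normalization, per the file headers and the values. The deposited standard error of that intensity over a probe's beads and the deposited number of beads per probe were used to judge noise within an array. The deposited detection p-value gives a probe's rank among the negative control probes of its array, in steps that imply 936 such probes. A further table holds the authors' processed values on a log2-like scale. Its 3 columns share the same quantiles, with a median of 6.79 in each, and each column keeps the rank order of its own array's intensity. It is not centred on genes, and higher means brighter on every array. Per the submitters' processing notes lumi was used, with no version given, and the transform is not given in the sources used here. That table served as an alternative. The series table also holds 10 columns of 2 further arrays that match none of the samples, and these were not used here in any step. A total of 2 lines that name no probe were left out.

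Of 45281 probes, the platform annotation gives 34885 a single gene, 18 several genes and 10378 none, and 34807 were matched by gene identifier to NCBI's mouse gene table of assembly GRCm38.p6, which changed 0 symbols. Probes with several genes were not named. Genome coordinates were not used here. List members under an older symbol were followed to the current one only where the older name is no gene's current symbol. That rule replaced a looser one after values had been seen, and the closing section gives its effect.

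Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative controls inferred from the detection p-values. A probe was tested if its detection p was under 0.01 on at least 1 of the 3 arrays, which left 18175 probes, and the brightest probe stood for each of 10300 genes. Differences are CD24+CD90+ minus the mean of the CD24+CD90- arrays in log2 units. They were fitted with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit has 1 residual degree of freedom per gene and a prior of 5.03, and the lone CD24+CD90+ array is assumed to vary like the CD24+CD90- arrays. A separate size rule with no test counts genes for which the CD24+CD90+ value lies at least 2-fold outside both CD24+CD90- arrays. Where no probe of a gene was detected on any array of a group, the fold is given as a lower bound against the lowest detected signal of those arrays. The number of arrays limits the precision.

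A total of 29 gene lists were fixed before the data were examined. For each, the median difference was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins with matrixStats 1.5.0. A list stands apart below percentile 2.5 or above 97.5. This describes these arrays and is not a test of the populations. Limma's camera was run as an alternative, with a preset correlation of 0.01 and with an estimated one. The estimate rests on 1 residual degree of freedom, so that version could hardly call any list, and its lack of calls decides nothing. Genes named in the text are the sort and depletion markers, the 10 largest rises and the 10 largest falls past both the adjusted p and the size rule, up to 4 genes per list by absolute difference, and Axl, Thbs2, Postn, Vim, Cdh1 and Epcam. Predicted or unnamed transcripts were left out of the places for rises and falls, where 21 and 15 such genes met the rule. Any other gene named in the text was chosen after its values were seen.

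The limma step was checked on data simulated for this comparison, with 10300 genes at the real levels and the fitted spread, over 20 rounds. With 200 genes changed, 0.8% were recovered at 1.41-fold, 11.2% at 2-fold, 94.5% at 4-fold and 99.8% at 16-fold, and 10.1% of calls were false against a nominal 5%. With 3500 genes changed, 81.9% were recovered at 2-fold and 3.58% of calls were false. Every simulated array had the same spread and no normalization step. These rates therefore do not carry over to the real calls if the lone CD24+CD90+ array varies otherwise. The list percentile was checked on 500 simulated lists of 20 genes from 10300, each against 1000 random lists. Of these, 4.2% stood apart when unchanged, and 89.8% did when shifted by 1 log2 unit. The simulated genes varied independently, whereas members of a real list can vary together, so the rate for real lists may differ. Alternatives covered the background correction, the normalization, the detection filter, the probes of a gene, the prior variance, the thresholds, the list test and each CD24+CD90- array left out.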

Results

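Gene expression was measured in cancer cells sorted from primary MMTV-PyMT mammary tumours, on 2 arrays of CD24+CD90- cells and 1 array of CD24+CD90+ cells. The labels title the CD24+CD90+ sample as cancer stem cells and the others as non-stem cells. Of 45281 probes, 16092 and 15339 were detected on the CD24+CD90- arrays and 15162 on the CD24+CD90+ array. A probe was read from a median of 43, 42 and 40 beads on these arrays. Across 10300 genes, which are not independent replicates, the CD24+CD90- arrays correlated with each other at a Pearson r of 0.989 and with the CD24+CD90+ array at 0.836 and 0.837. The labels list the CD24+CD90- arrays as separate samples, and they were counted as 2. The CD24+CD90+ group has no replicate, so its own spread was not measured.

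Thy1, which encodes CD90 and was used for sorting, checks the labels. Its normalized log2 intensity was 5.02 and 5.27 on the CD24+CD90- arrays and 12.53 on the CD24+CD90+ array, a difference of 7.39 ± 0.22 (fitted SE, limma adjusted p = 4.38e-05). The probe for Cd24a was not detected on any array, so the CD24 gate could not be checked. No probe of Ptprc, which encodes the depletion marker CD45, was detected either. Pecam1, which encodes the depletion marker CD31, was lower in CD24+CD90+ cells by a log2 difference of -0.99 ± 0.21 (limma adjusted p = 0.0165), or -0.33 in the authors' table, and it passed in 6 of 8 alternatives (adjusted p from 0.00689 to 0.0848), not in the authors' table or over the mean of its probes.

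The largest rises in CD24+CD90+ cells were much larger than the largest falls. Among the largest rises besides Thy1 were those of the matrix metalloproteinase genes Mmp13 (7.22 ± 0.20) and Mmp3, which only 1 of the 2 CD24+CD90- arrays detected (7.64 ± 0.21, or 5.57 in the authors' table). Others were those of Fn1, which encodes fibronectin (7.17 ± 0.31, but 3.85 over the mean of its probes), and of Lum, which encodes the collagen-binding proteoglycan lumican (6.73 ± 0.21). Pcolce (detected on 1 of the 2 CD24+CD90- arrays), Serping1, Pla1a and Cpxm1 rose by 6.52 to 6.67, and Tnxb, not detected in CD24+CD90- cells, was at least 84.6-fold higher (24.1-fold in the authors' table, whose scale is compressed at low values). The largest fall was that of Glycam1 (-3.64 ± 0.20), a mucin-like milk component, followed by the kallikrein genes Klk1b9, Egfbp2, Klk1b21, Klk1b22, Klk1b11 and Klk1b27 (-3.13 to -2.75), of which Klk1b9 and Egfbp2 had -2.06 and -1.71 in the authors' table. Klk1b8 was at least 8.14-fold lower and Egf at least 5.67-fold lower in CD24+CD90+ cells, where neither was detected, but in the authors' table they were 2.95-fold and 2.34-fold lower. Btn1a1, which encodes butyrophilin of the milk fat globule, fell by 2.72 ± 0.21. Probes for the near-identical Klk1b genes can share signal, so their separate values are uncertain. Each of these genes had a limma adjusted p of 0.00168 or less.

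By limma, 1663 genes were higher and 1838 lower in CD24+CD90+ cells at an adjusted p under 0.05, together 33.99% of the 10300 tested, and 4743 genes had an unadjusted p under 0.05. Higher genes were 47.5% of the calls, and 57.8% when arrays were scaled to a common median, which moved the median of all genes from -0.20 to -0.06. A total of 1158 genes lay at least 2-fold above both CD24+CD90- arrays and 693 at least 2-fold below. With either CD24+CD90- array taken as the single one, the counts were 8 above and 4 below, and 7 above and 3 below. These counts also need the array to lie outside the CD24+CD90+ array, so they can understate the background. In the simulated data, 27.2 unchanged genes on average met the 2-fold rule with 200 genes changed, and 19.4 with 3500 changed. At 16-fold or more the counts were 188 above and 0 below. Of the 1158 genes, 418 were detected on neither CD24+CD90- array. Of 28 gene lists with tested members, 14 stood apart as higher and 6 as lower, while camera called 0 higher and 0 lower with an estimated correlation and 13 and 6 with the preset one. The preset calls leave out the stem and Schwann lists (adjusted p = 0.437 and 0.417) and take in the oxidative phosphorylation list, which did not stand apart. The 2-fold counts fell to 728 above and 213 below without background correction, and to 683 above and 198 below in the authors' table.

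**Figure D1:**
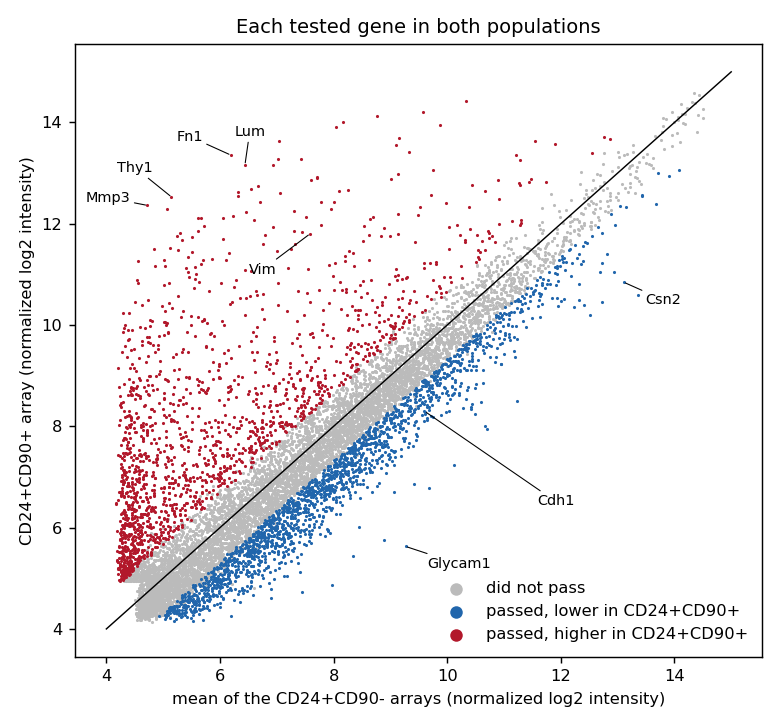
Each point is 1 of 10300 tested genes, with its mean normalized log2 intensity on the 2 CD24+CD90- arrays on the x axis and its value on the CD24+CD90+ array on the y axis, and the line marks equal values. The 1663 genes that passed the limma threshold as higher reach much farther from the line than the 1838 that passed as lower.

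Mesenchymal, matrix and fibroblast genes rose together. All 19 tested members of the list of EMT regulators and mesenchymal markers rose (19 when adjusted over the list alone), with a median difference of 4.09, or 3.91 with undetected genes at their bound, and of 2.36 in the authors' table and 2.49 without background correction. They included Vim, the mesenchymal intermediate filament gene (4.22 ± 0.21), Lox, which encodes a collagen cross-linking oxidase (5.91 ± 0.21), and Sparc (4.63 ± 0.21). Of 26 collagen and matrix genes, 25 rose (26 when adjusted over the list alone), with a median of 5.07 (5.02 at bounds), among them Col6a2 (6.36 ± 0.24) and Thbs2, which encodes thrombospondin-2 (5.25 ± 0.20). Col11a1 (0.72, or 0.22 in the authors' table), detected on 1 of the 2 CD24+CD90- arrays, did not pass, but did in 1 of 7 alternatives (adjusted p from 0.0143 to 0.202). All probes of Postn were undetected. All 19 matrix remodelling genes rose (19 when adjusted over the list alone; median 4.65), including the protease gene Ctsk (6.31 ± 0.20) and Loxl1 (6.26 ± 0.20). All 17 fibroblast markers rose as well (17 when adjusted over the list alone; median 5.36, or 5.09 at bounds), among them Pi16 (6.49 ± 0.22), Col14a1 (6.32 ± 0.21, detected on 1 of the 2 CD24+CD90- arrays) and Dpt (6.23 ± 0.26), and 9 of the 17 also stand in another list. These 4 lists each stood at percentile 100 of random lists. None passed camera with an estimated correlation, a version that rests on 1 residual degree of freedom and could hardly call any list.

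Epithelial, luminal and milk genes were lower. Of 25 genes for epithelial junctions and their regulators, 20 fell and 0 rose (20 when adjusted over the list alone), with a median of -1.28 (-1.26 at bounds). Cdh1, which encodes E-cadherin, fell by 1.32 ± 0.21 and the splicing regulator gene Esrp2 by 1.70 ± 0.21, while the probe for Epcam was not detected. Of 16 luminal genes, 12 fell and 1 rose (13 and 2 when adjusted over the list alone; median -1.06), with falls of Elf5, a transcription factor of alveolar cells (-1.83 ± 0.21), of Kit (-1.70 ± 0.20) and of the keratin gene Krt19 (-1.57 ± 0.20). The riser was the oestrogen receptor gene Esr1 (0.74, or 0.21 in the authors' table), which was detected on 1 of the 2 CD24+CD90- arrays and passed in 4 of 7 alternatives (adjusted p from 0.00636 to 0.185). Of 14 milk genes, 11 fell and 0 rose (11 when adjusted over the list alone; median -1.89), among them the casein gene Csn2 (-2.26 ± 0.20) and Lalba, which encodes alpha-lactalbumin (-2.24 ± 0.26). These 3 lists stood at percentile 0. Camera with an estimated correlation gave an adjusted p of 0.306 for the junction and milk lists and 0.489 for the luminal list. On the same array the fibroblast markers were higher by a median of 5.36.

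Basal and myoepithelial markers went both ways. Of 16 tested, 8 rose and 3 fell (8 and 3 when adjusted over the list alone), with a median of 0.83 at percentile 99.99, which was 0.41 in the authors' table and 0.23 with no detection filter. The risers included the smooth muscle actin gene Actg2 (3.21 ± 0.29, detected on 1 of the 2 CD24+CD90- arrays, and 1.64 in the authors' table), the transcription factor gene Snai2 (2.98 ± 0.31) and Mylk, which encodes a myosin kinase (2.29 ± 0.21), and Tagln was at least 3.65-fold higher (1.796-fold in the authors' table). The genes that fell were Lamb3 (-1.04), Itga6 (-0.88, or -0.38 in the authors' table) and Itgb4 (-1.26). Chosen after their values were seen, the basal keratin genes had differences of 0.36 for Krt5, -0.42 for Krt14 and 0.05 for Krt17, none past the threshold. Krt14 passed as lower in 2 of 8 alternatives (adjusted p from 0.0297 to 0.527). Without the members shared with another list the median was 0.079 at percentile 90.5. Camera with an estimated correlation gave an adjusted p of 0.349, and the fibroblast markers were higher by a median of 5.36.

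**Figure D2:**
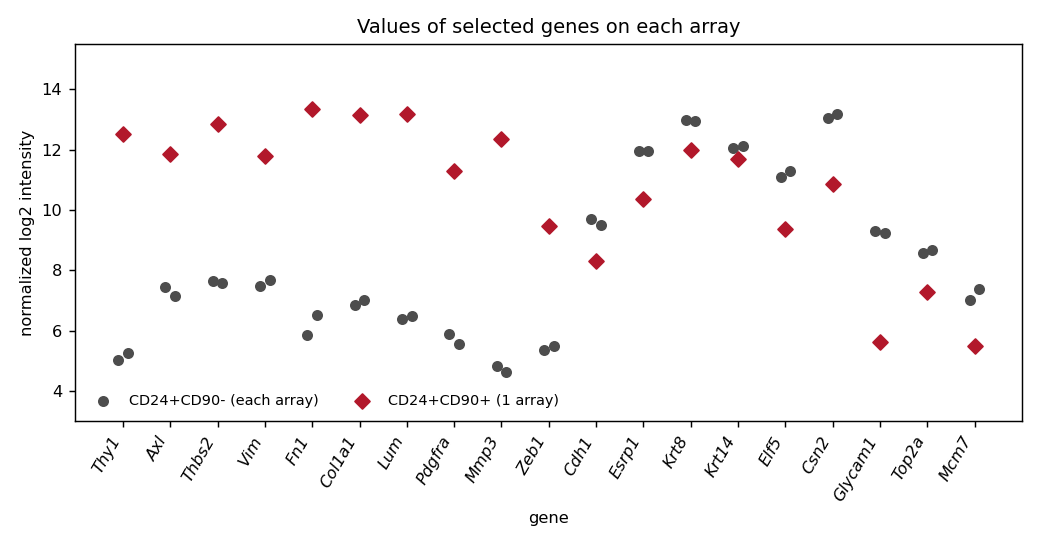
Normalized log2 intensity (y axis) on each array of genes chosen for display after their values were seen (x axis), with circles for the 2 CD24+CD90- arrays and a diamond for the CD24+CD90+ array. Thy1 rises from 5.02 and 5.27 to 12.53, whereas Cdh1 falls by 1.32 and Krt14 differs by -0.42.

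Cell cycle and lipid synthesis genes were lower. Of 29 cell cycle and DNA replication genes, 23 fell and 1 rose (24 and 1 when adjusted over the list alone), with a median of -1.18 at percentile 0. Hmgb2 fell by 1.97 ± 0.25, and Mcm7 (-1.71 ± 0.24, or -0.85 in the authors' table) and Mcm5 (-1.55 ± 0.21), which encode subunits of the replicative helicase, fell as well. The riser was Kif23 (5.18 ± 0.20), for which the other tested probes gave -0.41 and -0.67 and the mean of its probes 1.37, so its value is uncertain. Of 13 lipid and cholesterol synthesis genes, 10 fell and 0 rose (10 when adjusted over the list alone; median -1.01 at percentile 0.01), including Srebf1, a transcriptional regulator of lipid synthesis (-1.66 ± 0.23), and Elovl6 (-1.42 ± 0.20). Camera with an estimated correlation gave an adjusted p of 0.306 for both lists. On the same array the fibroblast markers were higher by a median of 5.36.

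Other metabolic and general lists did not stand apart by their percentiles. Of 25 oxidative phosphorylation genes, 6 fell and 0 rose (0 and 0 when adjusted over the list alone; 13 fell at an unadjusted p under 0.05; median -0.50 at percentile 4.06), among them Atp5a1 (-1.20 ± 0.24, or -0.80 in the authors' table). That list passed the limit without background correction, with an offset of 50 and in the authors' table (percentiles 1.22, 2.45 and 2.03), and camera called it lower with the preset correlation (adjusted p = 0.00292) but not with an estimated one (adjusted p = 0.307). Of 22 hypoxia and glycolysis genes, 4 rose and 5 fell (4 and 7 when adjusted over the list alone). Their median was -0.50 at percentile 3.16 (-0.29 in the authors' table) and their mean was 0.15. The risers were Adm, which encodes adrenomedullin (3.12 ± 0.25, or 1.70 in the authors' table), the collagen prolyl hydroxylase genes P4ha2 (3.36 ± 0.21) and P4ha1 and the kinase gene Pfkfb4, with Adm and Pfkfb4 detected on 1 of the 2 CD24+CD90- arrays. The glycolysis and glucose transport genes Pfkl, Aldoc, Slc2a1, Ldha and Pkm fell by 0.68 to 1.30, of which Ldha passed in 5 of 8 alternatives (adjusted p from 0.00286 to 0.0726) and Pkm in 4 (0.00279 to 0.147). The list passed the limit with no detection filter (percentile 1.61), among genes detected on all 3 arrays (percentile 2.135) and without members shared with another list (percentile 2.13). Of 19 unfolded protein response genes, 4 fell and 0 rose (4 when adjusted over the list alone; median -0.29 at percentile 38.1, -0.099 under median scaling, and -0.43 at percentile 9.78 without CD24+CD90- replicate 2), namely Trib3 (-1.66 ± 0.20), Sdf2l1, Asns and Xbp1. None of 20 ribosomal protein genes passed the limma threshold (0 when adjusted over the list alone; 3 fell at an unadjusted p under 0.05; median -0.31 at percentile 54.3). Rpl4, with a difference of -0.64 ± 0.20, passed in 5 of 8 alternatives (adjusted p from 0.00545 to 0.111). Of 11 housekeeping genes, 1 rose and 1 fell (1 and 1 when adjusted over the list alone; median -0.34 at percentile 45.4, and -0.18 without CD24+CD90- replicate 1), namely B2m (1.49 ± 0.23) and the transferrin receptor gene Tfrc (-1.58 ± 0.21).

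Signalling genes were higher on balance. Of 30 TGF-beta and BMP genes, 18 rose and 2 fell (19 and 2 when adjusted over the list alone; median 1.23, or 1.195 at bounds, and 0.62 in the authors' table), led by Fstl1 (5.74 ± 0.21) and Ltbp4, which encodes a latent TGF-beta binding protein (4.07 ± 0.20). Inhba was at least 10.05-fold higher (3.62-fold in the authors' table), while Id2 (-1.06) and Bmpr1a (-0.80, or -0.40 over the mean of its probes) fell, Bmpr1a in 5 of 8 alternatives (adjusted p from 0.0141 to 0.147). Of 24 Wnt pathway genes, 16 rose and 1 fell (17 and 1 when adjusted over the list alone; median 0.96 at percentile 99.99), including the secreted modulator genes Dkk3 (3.94 ± 0.25) and Sfrp2 (3.85 ± 0.23, or 2.31 in the authors' table), against a fall of Wnt5b (-1.18). The Wnt median was 0.41 in the authors' table and 0.19 at percentile 95.8 among genes detected on all 3 arrays. Of 30 receptor tyrosine kinase and ligand genes, 16 rose and 5 fell (18 and 7 when adjusted over the list alone; median 1.40, or 1.34 at bounds). Their median was 0.595 in the authors' table, 0.68 without background correction and 0.56 among genes detected on all 3 arrays. They included the receptor genes Axl (4.56 ± 0.23) and Pdgfra (5.57 ± 0.23), which rose, and Pdgfc, Pdgfb, Erbb2 and Kit, which fell by 0.78 to 1.70 (the first 3 by 0.43 to 0.596 in the authors' table), and Met was at least 2.62-fold lower (1.46-fold in the authors' table). Camera with an estimated correlation gave an adjusted p of 0.306 for these 3 lists. Of 13 stem and progenitor markers, 6 rose and 5 fell (6 and 6 when adjusted over the list alone; median 0.51 at percentile 99.45), with a rise of Klf4 (2.21 ± 0.20) and falls of Kit, Lgr6, Sox9, Itga6 and Notch1, the last in 6 of 8 alternatives (adjusted p from 0.00893 to 0.0996). The direction of that list did not hold, since it stood apart as lower among genes detected on all 3 arrays (median -0.75 at percentile 0.72). With no detection filter, a detection p under 0.05 or the mean of a gene's probes, it did not stand apart (percentiles 59.55, 74.1 and 31.4). The list did not pass camera with an estimated correlation either. Beside these lists the fibroblast markers were higher by a median of 5.36.

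Inflammatory and stress genes were also higher. Of 20 chemokine and cytokine genes, 14 rose and 2 fell (14 and 2 when adjusted over the list alone; median 1.45, or 1.25 at bounds), with a median of 0.595 in the authors' table but 2.496 among genes detected on all 3 arrays. They were led by the eosinophil chemoattractant gene Ccl11 (6.25 ± 0.24) and by Cxcl14 (5.44 ± 0.21). Cxcl15 was at least 1.51-fold (1.27-fold in the authors' table) and Csf3 at least 1.1-fold lower, which passed in 6 and 3 of 7 alternatives (adjusted p from 0.00335 to 0.0504 and from 0.0257 to 0.174). Of 24 interferon response and antigen presentation genes, 13 rose and 0 fell (13 when adjusted over the list alone; median 0.76, and 0.39 in the authors' table), such as Oasl2 (1.79 ± 0.20, or 1.07 over the mean of its probes). Of 22 immediate early and dissociation stress genes, 14 rose and 0 fell (15 and 1 when adjusted over the list alone; median 0.78, or 0.77 at bounds), including Gadd45b (2.39 ± 0.21) and the early transcription factor gene Egr2 (2.13 ± 0.20). The TGF-beta, receptor tyrosine kinase, chemokine, interferon and immediate early lists stood at percentile 100, and camera with an estimated correlation gave an adjusted p of 0.306 for each. On the same array the fibroblast markers were higher by a median of 5.36.

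Markers of other cell types moved unevenly, among them endothelial and leukocyte markers, whose cells the CD31 and CD45 depletion was meant to remove. Of 12 pericyte and vascular smooth muscle markers, 9 rose and 0 fell (10 when adjusted over the list alone; median 1.94, or 1.86 at bounds, at percentile 100), with a median of 1.01 in the authors' table and of 0.72 at percentile 98.9 among genes detected on all 3 arrays. They were led by Rgs5 (5.33 ± 0.23, detected on 1 of the 2 CD24+CD90- arrays, and 3.45 in the authors' table). Of 15 endothelial markers, 6 rose and 3 fell (6 and 3 when adjusted over the list alone; median 0.09 at percentile 83.3), with rises of Tek (3.21 ± 0.23) and Eng (2.45 ± 0.27), which had 1.73 and 1.29 in the authors' table. Those that fell were Pecam1, Robo4 (-0.90, or -0.396 in the authors' table) and Egfl7 (-0.998, or -0.61 over the mean of its probes), which passed in 7 of 8 alternatives (adjusted p from 0.00355 to 0.0536). Among genes detected on all 3 arrays that list stood apart with a median of 0.68 at percentile 99.85, and with no detection filter its median was -0.16. Of 15 myeloid and pan-leukocyte markers, 1 rose and 0 fell (1 when adjusted over the list alone; median 0.01 at percentile 77.5, and -0.10 without CD24+CD90- replicate 1), namely S100a9, at least 1.74-fold higher (1.27-fold in the authors' table), which passed in 6 of 7 alternatives (adjusted p from 0.000486 to 0.057) and not in the authors' table. None of the 10 lymphocyte markers with a probe was detected. Of 4 adipocyte markers, 2 rose (2 when adjusted over the list alone; median 0.56, or 0.33 at bounds, at percentile 93.7, and 0.15 in the authors' table), the lipoprotein lipase gene Lpl (3.44 ± 0.20) and Pparg, at least 1.42-fold higher (1.19-fold in the authors' table), of which Pparg passed in 4 of 7 alternatives (adjusted p from 0.00195 to 0.123). All 3 erythroid markers rose (3 when adjusted over the list alone; median 2.77 at percentile 99.9, and 0.77 with no detection filter), with Alas2 at least 2.08-fold higher (1.301-fold in the authors' table) and with Hba-a1 (2.92 ± 0.21) and Hbb-bs (2.77 ± 0.20), globin genes with near-identical copies whose separate values are uncertain. Of 4 Schwann and glial markers, 3 fell and 1 rose (3 and 1 when adjusted over the list alone; median -1.14 at percentile 0.44, and -0.56 in the authors' table), with Cdh19 at least 2.89-fold lower (1.54-fold in the authors' table), Sox10 at -1.47 ± 0.22, Mbp at -0.80 (-0.51 in the authors' table, passed in 5 of 8 alternatives, adjusted p from 0.0199 to 0.112) and Ngfr at 2.11 ± 0.20 (0.99 in the authors' table). That list did not stand apart with no detection filter (percentile 7.55) or among genes detected on all 3 arrays (percentile 6.61). Camera with an estimated correlation gave an adjusted p of 0.306 for the pericyte list, 0.307 for the erythroid list and 0.594 for the Schwann list. The fibroblast list had a higher median than any of these lists, 5.36.

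**Figure D3:**
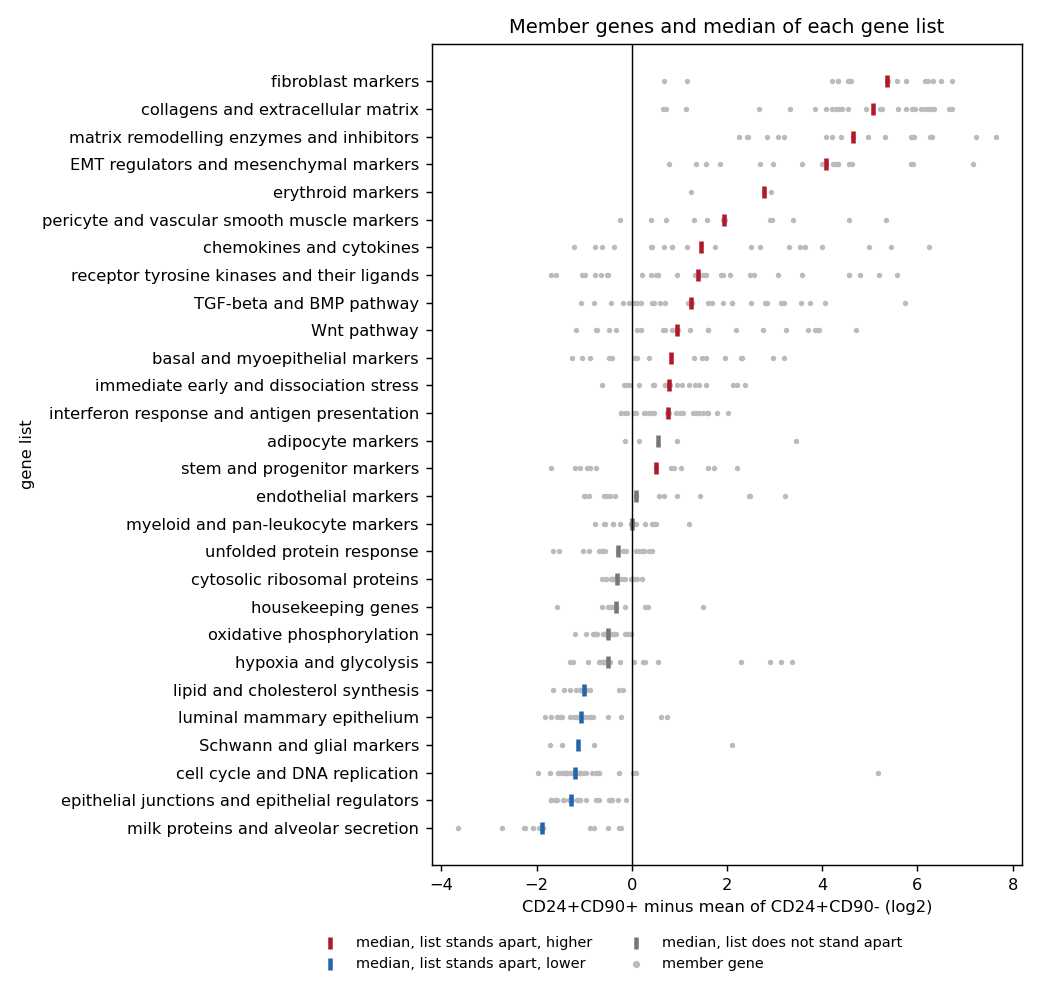
Difference between CD24+CD90+ and the mean of CD24+CD90- (x axis, log2) for each member gene (dots) of the 28 gene lists with tested members (y axis), with a vertical bar at each list's median. Fibroblast markers have the highest median, 5.36, and milk protein genes the lowest, -1.89.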

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

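The result given here is a signal in data that the comparisons between genes did not use, and its count was chosen after the data were seen. Among 2439 detected probes to which the annotation used here gives no single gene name, 176 lay at least 2-fold above both CD24+CD90- arrays on the CD24+CD90+ array, and 147 lay at least 2-fold below. With a CD24+CD90- array taken as the single one, the counts were 9 above and 0 below for replicate 1, and 16 above and 3 below for replicate 2. As for the named genes, such counts can understate the background. By the same rule, 1158 of 10300 named genes lay above and 693 below, which are no smaller shares. The unnamed probes therefore did not stand out from the named genes. They were not named, and no explanation was tested for them.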

How the results depend on the processing

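The alternatives were planned, except the cell cycle list without Kif23 and the looser symbol rule, which were chosen after seeing the data. Of 970 limma values of 125 named genes under the alternatives, 925 were the same in direction and side of the threshold, 30 newly passed the adjusted p and 14 no longer did. The difference of Adipoq, not past the threshold, changed sign to 0.054 under median scaling. Of 335 values of 28 lists, 319 were the same in whether and on which side the list stood apart, and 8 newly stood apart. A further 4 kept their sign but no longer stood apart, and 4, all of the stem and progenitor list, changed sign. Among lists that did not stand apart, the median changed sign in 2 alternatives for the endothelial and 4 for the myeloid list. The median of the stem and progenitor list, 0.51, became -0.067 with no detection filter (percentile 59.55) and -0.75 among genes detected on all 3 arrays (percentile 0.72). It became -0.0702 with a detection p under 0.05 (percentile 74.1) and -0.32 with the mean of a gene's probes (percentile 31.4). Of these settings, the list stood apart only among genes detected on all 3 arrays, as lower. The first 3 of these change which genes are tested. Counts moved by over 1.5 times as follows. Genes at least 2-fold above numbered 728 without background correction, 683 in the authors' table, 630 among genes detected on all 3 arrays and 620 at 4-fold. Genes at least 2-fold below numbered 213 without background correction, 352 with an offset of 50, 458 under median scaling, 198 in the authors' table, 1939 at 1.5-fold and 24 at 4-fold. Genes past the limma adjusted p numbered 1204 lower with no filter, where more genes are tested, and 1085 higher among genes detected on all 3 arrays, where fewer are. With an estimated correlation, camera called 0 lists higher and 0 lower, against 13 and 6 with the preset one. The estimate rests on 1 residual degree of freedom, so those missing calls decide nothing. The correlation of the CD24+CD90- arrays, 0.989, was 0.993 in the authors' table, 0.993 before normalization and 0.992 with no filter. Apart from the settings named as changing the genes tested or the threshold, the cause was not tested. Under the looser symbol rule 7 lists stood apart as lower against 6, since the hypoxia list moved to percentile 1.2. Without Kif23 the cell cycle median was -1.19. With a CD24+CD90- array left out, 1 array faces 1 and limma has no test, and 1265 to 1280 genes lay above and 972 to 976 below, with 14 lists apart as higher and 6 as lower. No paired analysis was possible because the CD24+CD90+ group holds 1 array. Genes near background are limited by signal, and their folds are bounds.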

Other observations

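The gene families below, and the tests of a fibroblast source, a mesenchymal state and dilution and that of background correction on cell cycle genes, were chosen only after the results were seen, and the other tests of normalization before. The 15 tested Hox genes had a median difference of 2.17. Hoxb7 (3.18) and Hoxb4 (2.51), with 1.55 and 1.202 in the authors' table, were each detected on 1 of the 2 CD24+CD90- arrays. Hoxa2, Hoxa5, Hoxa9, Hoxc6, Hoxc9, Hoxc10, Hoxd4, Hoxd8 and Hoxd9 were not detected in CD24+CD90- cells. These entered the comparison through the CD24+CD90+ array alone, and their folds are lower bounds, from 1.33-fold for Hoxa2 to 26.3-fold for Hoxc6. The 12 complement components and regulators taken had a median of 2.40, from 0.03 to 6.58, with C2 at 5.22 and C4b at 3.15, whose copy C4a is near-identical. Among them C1s1, Cfi, Colec12 and Masp1 were not detected in CD24+CD90- cells, so their differences are limited by signal. The set leaves out C1qa, C1qb and C1qc, which stand in the myeloid list. Of 6 insulin-like growth factor binding protein genes, 5 rose and 0 fell (median 3.38), with Igfbp4 at 4.54 and Igfbp2 at 4.04, and Igfbp5, at -0.20, did not pass. Of 6 glutathione peroxidase genes, 3 rose and 0 fell (median 2.16), with Gpx8 at 5.25 and Gpx3 at 4.41, while Gpx4 fell in 3 of the 4 other normalizations. The medians of these 4 families lay above 0 in the 4 other normalizations tried, the lowest being 0.78 for the Hox genes in the authors' table. On the same array the fibroblast markers were higher by a median of 5.36.

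Other families went down or both ways. Of 17 kallikrein genes, 14 fell and 0 rose (median -2.29, and -1.71 in the authors' table), and near-identical copies make their separate values uncertain. Of 10 prolyl and lysyl hydroxylase genes, 8 rose and 1 fell (median 1.87, and 0.94 in the authors' table), P3h3 at 4.77 (3.15 in the authors' table, detected on 1 of the 2 CD24+CD90- arrays) and P3h2 at -1.29 (-0.68 in the authors' table). Of 13 semaphorin genes, 5 rose and 2 fell, from 4.22 for Sema7a to -0.87 for Sema4b. Among cyclin D genes, Ccnd2 rose (4.21, or 2.72 in the authors' table), Ccnd1 fell (-1.06) and Ccnd3 did not pass (0.30).

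Fibroblast, matrix and mesenchymal genes were higher in the CD24+CD90+ array, and the tables argue against background correction or quantile normalization as the source, since the lowest median of the fibroblast list over 4 other normalizations was 4.25. Stromal fibroblasts carried in the sort are a candidate source: the 11 fibroblast markers in no mesenchymal, matrix or remodelling list had a median of 5.36 (95% bootstrap interval over members 4.33 to 6.23), and abundant fibroblast transcripts such as Dcn reached a log2 intensity of 13.69. The CD45 and CD31 depletion would not remove fibroblasts, and the CD24 gate, which might, could not be checked. A mesenchymal state of the cancer cells is the other candidate, since the 18 mesenchymal markers outside the fibroblast list had a median of 4.07 (2.98 to 4.45). Both stay open, because each test was chosen after the rises were seen and neither could separate these sources. The bootstrap intervals here and below resample member genes on the same arrays. They hold no spread between arrays or animals and do not measure how surely the populations differ.

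Epithelial genes were lower in the CD24+CD90+ array. Under median scaling the junction list lay at -1.04 relative to the median of all genes. A shift common to all genes drops out of that measure, so it cannot test for one. Without that subtraction, the highest junction median over 8 alternatives, median scaling among them, was -0.856 in the authors' table. This argues against quantile normalization as the whole source of the junction fall. Dilution of unchanged CD24+CD90- cells by cells without basal genes predicts equal falls. The 8 epithelial members of the basal list had a median of -0.45 against -1.28 for the junction list. This set leaves out the 8 basal list members at least 2-fold above both CD24+CD90- arrays. Its median therefore does not describe the whole list, whose 16 tested members had a median of 0.83. The 95% bootstrap interval over members of the difference of 0.82 (0.20 to 1.39) lies above 0 but holds the limit of 0.5. Luminal and milk genes had medians of -1.06 and -1.89. By that limit the test cannot tell whether dilution by a common factor is the whole source for these genes. The luminal and milk medians were not tested against the junction median. After the values were seen, this set was widened from 5 genes that did not pass by limma, whose difference was 1.325 (0.671 to 1.635), to take in Lamb3, Itga6 and Itgb4, which fell, and the interval replaced a 2-sided permutation p of 0.00964 (100000 permutations), as it replaced one in the cell cycle test below. The interval of the 5 genes first used lay wholly beyond the limit of 0.5. Dilution by a mixture that holds basal cells, and lower expression in the CD24+CD90+ cancer cells, stay open and were not tested.

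Cell cycle genes were lower in the CD24+CD90+ array. Under median scaling the list lay at -0.995 relative to the median of all genes, a measure from which a common shift drops out. Without that subtraction, its highest median over 8 alternatives, median scaling among them, was -0.826 in the authors' table. This argues against quantile normalization as the whole source. Relative to the median of all genes, the list lay at -0.756 without background correction (95% bootstrap interval over members -0.849 to -0.529, against a limit of -0.5). In the authors' table it lay at -0.733 by the same measure. These values argue against background correction as the whole source. Dilution of cycling epithelial cells by cells that do not cycle stays a candidate explanation. The cell cycle median differed from the junction median by 0.092 (95% bootstrap interval over members -0.227 to 0.334), within the limit of 0.5. That closeness decides nothing, because the junction fall was not shown to be dilution, and luminal and milk genes had medians of -1.06 and -1.89. Slower cycling of the CD24+CD90+ cancer cells stays open as well and was not tested.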
